A study of Homo sapiens with 12 samples.

How the data were processed

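The series holds 12 samples of the fibroblast line MRC5 in 4 groups of 3: control, TGF-β1, cyclosporine, and both. Total RNA was labelled with 1 dye and hybridised to 4-plex whole human genome arrays on 3 slides, so that each slide held 1 array of every group. The deposited scanner files were made by the authors with Agilent Feature Extraction 9.5.3 as the submitters state it, and the file headers give 9.5.3.1 for slide 1 and 9.5.1.1 for slides 2 and 3. Per the file headers, the processed signal is a background-subtracted intensity on a linear scale. The deposited value table holds the same intensity, and it equals the scanner files in 43376 of 43376 non-control spots on every array. The header of each file also gives the scanner, which was 1 instrument for slide 1 and another for slides 2 and 3.

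Each array has 45015 spots, of which 1639 are controls. Of the remaining 43376 spots, those with a non-uniformity or population outlier flag were removed, and the spots of 1 probe were averaged on the log2 scale, giving 41000 probes. The log2 processed signal had the 75th percentile of its array subtracted. A probe entered when it was well above background on all arrays of at least 1 group, which 25770 did, and 21969 were so on every array. Probes were matched to current gene symbols through a RefSeq table of assembly GRCh38.p14: 23680 by accession, 2802 by symbol and 1128 by synonym, while 13390 kept the name in the file. Gene names differed at 6226 non-control spots between the 2 design versions in the files, which also mix genome builds, so no coordinates are given. The brightest probe stood for each gene. At most 2 missing values per gene were allowed, which removed 4 probes and left 18989 genes. Among other tested probes of called genes, 104 of 105 for TGF-β1 against control, 120 of 127 for both agents against control and 47 of 49 for both against cyclosporine had the sign of the brightest, and none passed with the opposite sign.

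The depth of an array is its signal over background. From 58.4% to 73.4% of probes were well above background on 11 arrays and 92.0% on TGF-β1 plus cyclosporine replicate 3. Median signals were 65.8 to 265 on the former and 825 on the latter, and 75th percentiles 605 to 2453 and 1880. limma's array weight for that array was 0.106, against 0.527 to 2.16. All 12 arrays stayed in the fit, and values without that array are given beside those with it for some lists and genes, not for all.

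Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit of 4 group means over the 12 arrays, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. There were 6 comparisons: each of the single agents and the combination against control, the combination against each single agent, and the interaction. The response to each agent was also set against itself with and without the other, by Pearson correlation and a total least squares slope. The camera test of limma, with a preset correlation of 0.01 between genes, was run on 26 gene lists and adjusted over the lists of a comparison; camera with an estimated correlation and the self-contained test fry stood beside it. The lists cover collagen chains, collagen processing, non-collagen matrix, contractile genes, TGF-β feedback, the BMP pathway, metalloproteinases, protease inhibitors, calcineurin and cyclophilins, NFAT, endoplasmic reticulum stress, the amino acid response, cholesterol synthesis and the cell cycle. They also cover cytokines, interferon response, glycolysis and hypoxia, antioxidant and NRF2 targets, p53 targets, lipofibroblast genes, the Wnt pathway, glycosaminoglycan synthesis, integrins, and epithelial, endothelial and leukocyte markers. Comparisons, lists and the rule for naming genes were written before the data were examined.

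The rule named the 8 largest rises and 8 largest falls among called genes with a symbol whose arrays did not overlap between the groups, up to 4 called members of each list by absolute fold change, and genes fixed for every comparison, among them ACTA2, COL1A1, FN1, CCN2, MMP1, TIMP1 and RCAN1. Where fewer than 5 genes passed, the 5 with the smallest p were named. Some genes that the rule names are not reported here. A gene below background on every array of a group has its fold given as a lower bound against that background. The bound takes no account of the spread between arrays or of the array that stands apart. A gene below it on only some arrays of a group keeps its value, which is then less certain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

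The labels do not say that a replicate number marks a shared day, and the fit set out in advance holds no block. Each slide held 1 array of every group, however. The main counts, SEs and p-values thus leave out a pairing by slide that the design has. After subtracting group means, arrays of the same number correlated at 0.178 to 0.836 (median 0.470, 18 pairs) and arrays of different numbers at −0.669 to 0.0354 (median −0.257, 36 pairs). The subtraction makes the deviations within a group cancel out, which pushes the values for different numbers to the negative side. Their negative sign is therefore no evidence of pairing by itself. The replicate number is also the slide number, and blocked values are given where they change a call or move a count by more than 1.5 times.

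The fit was tested on simulated data of 18946 genes in 3 runs, with 600 changed genes per size. For TGF-β1 against control it recovered 15.7% of 2-fold, 68.3% of 4-fold and 86.8% of 8-fold changes, and for cyclosporine against control 13.2%, 70.3% and 85.8%. With the slide block and without the array that stands apart, the recovery for these 2 comparisons was 76.3%, 96.8% and 99.0%, and 74.2%, 96.5% and 99.0%. In 20 runs with no change the mean number of genes called was at most 0.15. The noise in these runs, and in the recovery runs of the main fit, was independent between arrays and of equal variance on every array. It held no slide effect and no array that stands apart, whereas the real arrays show both. The recovery and the false calls therefore describe such simulated data and may differ in the real data.

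Alternatives were quantile normalization, model-based background correction (normexp, offset 50) with either scaling, no filter or a filter on all 12 arrays, the mean of a gene's probes, the value table, a threshold of 0.01 or an added doubling, trended and robust variances, array weights, only the groups compared, the replicate or slide block, both other list tests, and leaving out each array. Leaving out the array that stands apart where it is in neither group, and joining that to the block, were added after seeing the data. Transcript lengths and probes without a gene name in the design were not studied.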

Results

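Gene expression was measured in MRC5 cells, a human fetal lung fibroblast line, with 1-colour Agilent whole human genome arrays. The cells were serum-starved for 24 h and then left untreated (control), given 3 ng/ml TGF-β1, given 2 µg/ml cyclosporine, or given both agents, and RNA was taken at 48 h. Each of the 4 groups had 3 arrays, 12 in all, and replicates 1, 2 and 3 of every group lay on slides 1, 2 and 3. TGF-β1 is the cytokine that turns fibroblasts into contractile, matrix-producing myofibroblasts. Cyclosporine binds cyclophilins and blocks the phosphatase calcineurin, and thereby the NFAT transcription factors. The comparisons ask how each agent changed the transcriptome, and whether cyclosporine changed the response to TGF-β1. After filtering, 18989 genes were tested, of which 13376 carried a current gene symbol. Values below are log2 fold changes ± SE with n = 3 arrays per group, and the number of arrays limits their precision. The series text speaks of independent experiments. The fit has no slide term, so its SEs and p-values measure the spread between these arrays with the differences between slides included.

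The array of TGF-β1 plus cyclosporine replicate 3 stood apart from the other 11. Its median processed signal was 825, against 65.8 to 265 on the others, and 92.0% of its probes were well above background, against 58.4% to 73.4%. Its median Spearman correlation with the other arrays across probes was 0.855, against 0.949 to 0.965. It is 1 of the 3 arrays in each comparison of the combined treatment below, and it adds to the pooled spread in every comparison.

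**Figure D1:**
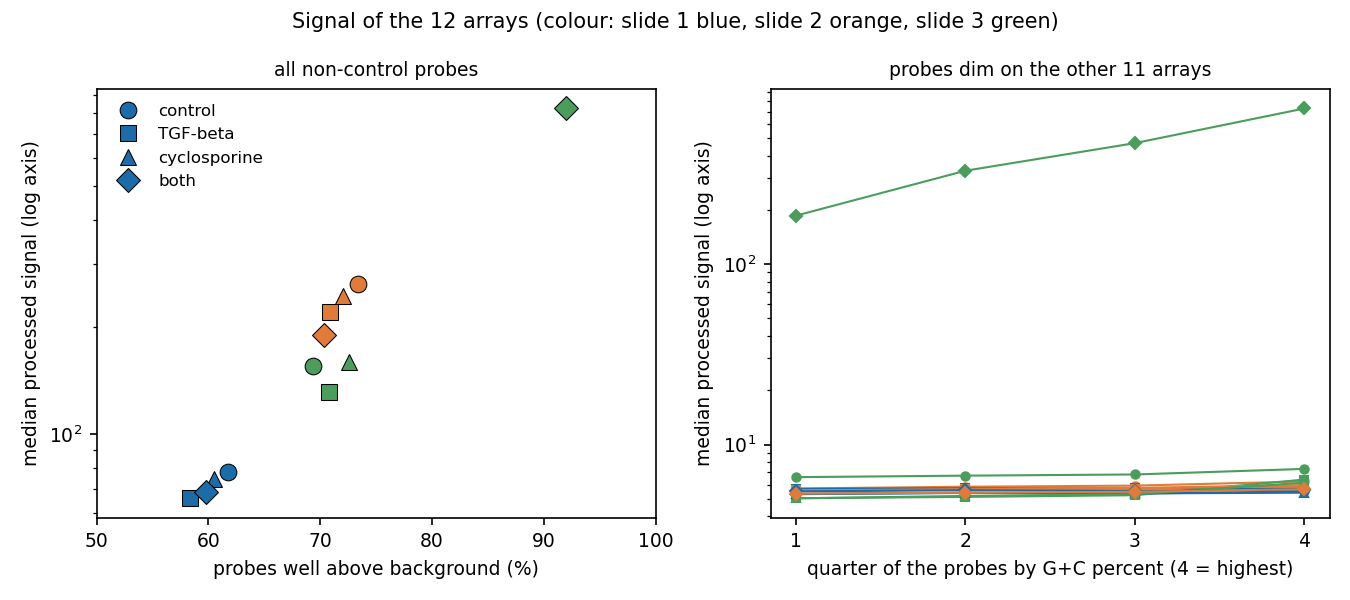
Left, median processed signal of each array (log axis, intensity units) against the percent of probes well above background; right, median signal (log axis) of probes that were dim on the other 11 arrays, in 4 equal classes of G+C percent, with marker shape for the group and colour for the slide. The array of TGF-β1 plus cyclosporine replicate 3 lies alone at 92.0% and 825, and its dim probes rise from 186 in the lowest class to 730 in the highest.

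TGF-β1 alone changed 298 of 18989 genes against control, 158 upward and 140 downward, and 297 of them had 1 sign on all 3 slides. As the genes were called on these same arrays, that shared sign was largely set by the choice. COMP, the cartilage oligomeric matrix protein, rose by 7.74 ± 0.96 (214-fold, adjusted p = 0.0068). PRG4, which encodes the lubricant lubricin, was below background on every control array (mean −7.71, against 0.21 with TGF-β1) and rose at least 66.9-fold. SYTL5, a synaptotagmin-like protein of vesicle transport that was well above background on 1 of 3 control arrays, rose by 6.08 ± 0.65. The steepest falls were those of SLC7A14, a transporter-family protein, at −6.86 ± 0.68, and of VCAM1, the leukocyte adhesion molecule, at −5.92 ± 1.12.

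Genes below background on every control array gave lower bounds. TYRP1, a melanosome enzyme, rose at least 19.8-fold (mean −7.50 in control, −1.55 with TGF-β1, adjusted p = 6.0e-05). The prostaglandin transporter SLCO2A1 rose at least 42.8-fold (−6.11 to −0.44), PI16 at least 20.7-fold (−6.81 to −1.48), and SPP1, which encodes osteopontin, at least 13.5-fold (−7.11 to −2.10). The other large falls were FGL2 (−4.99 ± 0.61), the scavenger receptor COLEC12 (−4.97 ± 0.81), the hyaluronan-degrading protein CEMIP (−4.52 ± 0.78), the growth factors PDGFD (−4.49 ± 0.84) and GDF5 (−4.08 ± 0.52), and the complement component C7 (−3.97 ± 0.73).

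Among 32 genes of TGF-β feedback and immediate targets, 11 rose and none fell, and 13 rose and 3 fell when adjusted over the list alone. NOX4, an NADPH oxidase, rose by 4.82 ± 0.67, the repressor BHLHE40 by 3.09 ± 0.51, the sphingosine kinase SPHK1 by 2.70 ± 0.56 and the cell cycle inhibitor CDKN2B by 2.53 ± 0.50. The list as a group lay above the other genes (camera adjusted p = 2.4e-06; adjusted p = 0.0982 with an estimated correlation). Of 22 collagen chains, 3 rose and none fell (5 and 2 adjusted over the list alone): COL10A1 by 2.75 ± 0.50, COL7A1 of the anchoring fibrils by 1.74 ± 0.33 and COL4A2 of basement membranes by 1.27 ± 0.25. Their median was 0.61 (camera adjusted p = 0.0014; adjusted p = 0.464 with an estimated correlation). Of 26 genes of collagen processing, the prolyl hydroxylase subunit P4HA3 alone was called, rising by 1.52 ± 0.26, and 3 rose and 1 fell adjusted over the list alone (median 0.39, camera adjusted p = 0.0050; adjusted p = 0.464 with an estimated correlation). The 45 non-collagen matrix genes went both ways: 6 rose and 5 fell (10 and 9 adjusted over the list alone), among them MFAP5 of microfibrils (well above background on 1 of 3 control arrays) at 4.11 ± 0.86, the basement membrane linker NID2 at −2.77 ± 0.43 and fibrillin-2, FBN2, at −2.49 ± 0.43, with camera adjusted p = 0.207. Of 29 contractile genes only CDH2, N-cadherin, was called, rising by 3.41 ± 0.37, and 2 rose adjusted over the list alone (list median 0.21, camera adjusted p = 0.0036; adjusted p = 0.621 with an estimated correlation). The contractile median was 0.11 and −0.02 without TGF-β1 replicates 2 and 3, where the list no longer passed camera, and 0.56 without replicate 1. The collagen processing list did not pass without TGF-β1 replicate 2.

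Inflammatory and antiviral genes lay lower. Of 25 cytokines and inflammatory mediators, VCAM1 fell and TNFAIP6, a hyaluronan-binding protein, rose by 2.84 ± 0.35, and 8 fell and 1 rose adjusted over the list alone (median −1.13, camera adjusted p = 2.5e-04; adjusted p = 0.26 with an estimated correlation). Of 26 interferon response genes, IFIT1 fell by 3.76 ± 0.64 and 23 had a negative fold change (5 fell adjusted over the list alone; camera adjusted p = 1.2e-05; adjusted p = 0.0555 with an estimated correlation). Of 26 antioxidant and NRF2 target genes 1 fell, with a list median of −0.63 (2 fell adjusted over the list alone; camera adjusted p = 4.2e-05; adjusted p = 0.464 with an estimated correlation). Genes of the amino acid response had a median of 0.37 although their only called member of 37, STC2, fell by 1.49 ± 0.28 (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.4e-06; adjusted p = 0.464 with an estimated correlation). In the glycolysis and hypoxia list of 24, the vasodilator peptide ADM fell by 3.11 ± 0.58 and ANKRD37 rose by 1.30 ± 0.28 (3 rose and 1 fell adjusted over the list alone; median 0.38, camera adjusted p = 9.4e-04; adjusted p = 0.559 with an estimated correlation). No member of the 25 endoplasmic reticulum genes or of the 14 integrins passed over all genes (0 and 1 adjusted over the list alone), while the lists lay higher by camera, with adjusted p = 9.4e-04 and 0.0015, and adjusted p = 0.621 and 0.26 with an estimated correlation.

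The other 15 lists did not pass camera (adjusted p = 0.0669 to 0.925), though several held called members. They included ID3 (2.17 ± 0.43) and ID1 (1.66 ± 0.33) of the BMP list, and the Wnt receptor FZD8 (4.89 ± 0.59). Others were the transcription factor EGR2 (4.17 ± 0.79) of the NFAT list and XYLT1, which starts glycosaminoglycan chains (3.47 ± 0.33). The sulfotransferase CHST15 (well above background on 1 of 3 TGF-β1 arrays) fell by 1.80 ± 0.38 and the protease ADAMTS1 by 2.28 ± 0.42, while the protease inhibitors SERPINE2 and TIMP1 rose by 2.07 ± 0.26 and 1.95 ± 0.41. List medians were −0.26 for the BMP pathway, −0.23 for matrix metalloproteinases, −0.40 for protease inhibitors, 0.05 for calcineurin and cyclophilins, 0.16 for NFAT factors, −0.04 for cholesterol synthesis and −0.38 for the cell cycle. They were −0.20 for p53 targets, −0.74 for lipofibroblast genes, −0.39 for Wnt genes and 0.15 for glycosaminoglycan synthesis. Markers of other cell types had medians of −0.09 (epithelial, 11 genes), 0.20 (endothelial, 7) and 0.38 (leukocyte, 7), with KRT18 (2.18 ± 0.41) and CSF1R (3.88 ± 0.68) called.

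Among the genes fixed for every comparison, TIMP1 was called (adjusted p = 0.0471). FN1, fibronectin, gave 0.99 ± 0.27 (adjusted p = 0.132; 0.034 with the slide as a block). The smooth muscle actin gene ACTA2 gave 1.14 ± 0.96, with −0.30 on slide 1, 2.53 on slide 2 and 1.18 on slide 3, and COL1A1 gave 0.53 ± 0.42, with −0.52, 1.16 and 0.94. CCN2, MMP1 and the calcineurin-regulated RCAN1 gave 0.08 ± 0.34, 0.43 ± 1.52 and −0.57 ± 0.22. RCAN1 did not pass in this fit but did in at least 1 of the other settings. The sign of CCN2 turned to −0.02 after model-based background correction. MMP1 gave 2.84, −0.87 and −0.67 on slides 1, 2 and 3, and −1.42 without TGF-β1 replicate 1. Slide 1 stood apart in the gene groups too: the medians of collagen chains were −0.01, 1.05 and 0.87 on slides 1, 2 and 3, those of contractile genes −0.42, 0.67 and 0.34, and those of cell cycle genes 1.07, −1.14 and −0.99. Across genes, which are not independent replicates, the fold changes of slide 1 correlated with those of slides 2 and 3 at 0.498 and 0.463, and slides 2 and 3 with each other at 0.825.

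With the slide as a block, limma called 648 genes, which included all 298. Leaving out the array that stands apart gave 580 genes, and the block without that array 2787, both chosen after seeing the data. The count was 49, 48 and 164 without control replicates 1, 2 and 3, and 485, 54 and 53 without TGF-β1 replicates 1, 2 and 3. Quantile normalization gave 187 genes, split 122 upward and 65 downward, and with only the compared groups in the fit 216 passed, 67 upward and 149 downward.

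**Figure D2:**
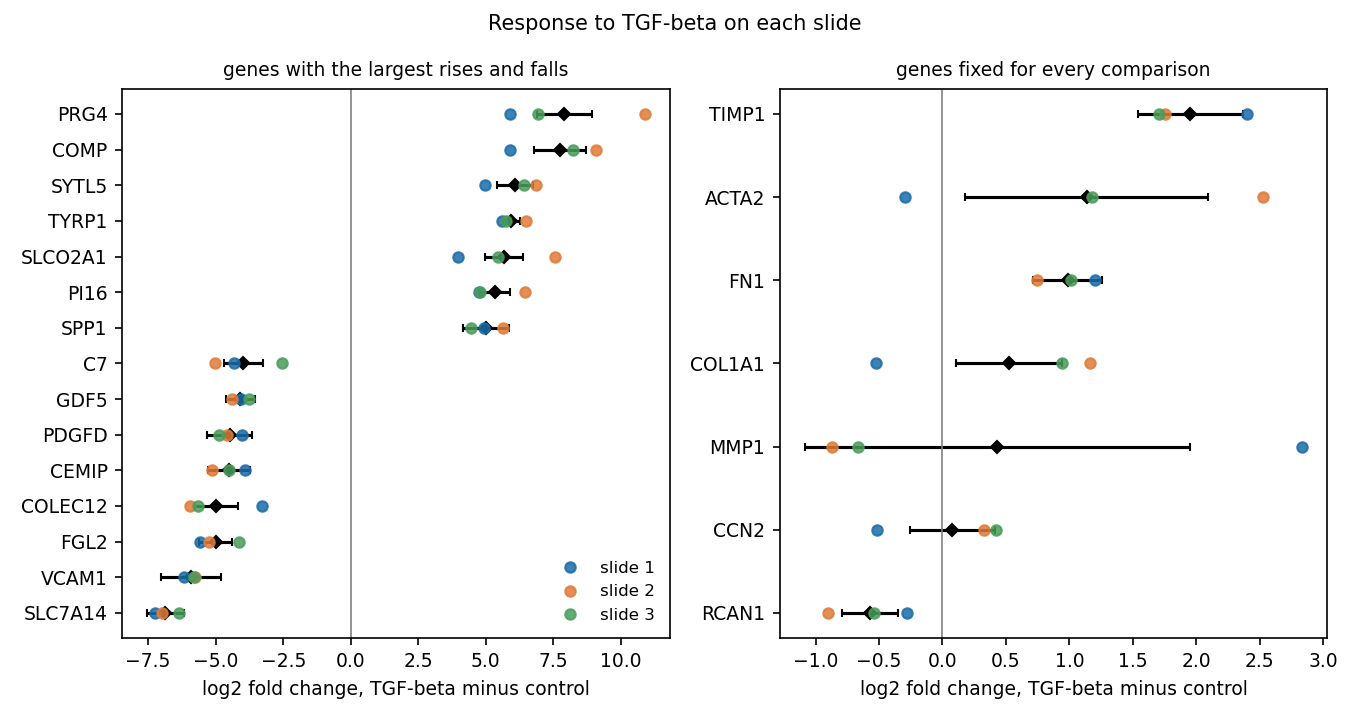
Log2 fold change of TGF-β1 minus control for genes with the largest rises and falls (left) and for genes fixed for every comparison (right); diamonds with bars are the mean ± SE of 3 arrays per group, and coloured points the difference on each slide. ACTA2 lies at −0.30 on slide 1 and at 2.53 and 1.18 on slides 2 and 3. TYRP1 and SYTL5 lie above 0 on all 3 slides, which the naming rule of no overlap between groups fixed.

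Cyclosporine alone left no gene past the threshold on its own, while 10 gene lists passed camera with its preset correlation. With an estimated correlation the cytokine list alone passed (adjusted p = 0.0188; 0.161 with the slide as a block), and the endoplasmic reticulum and contractile lists gave adjusted p = 0.106 and 0.207. All 25 measured genes of the endoplasmic reticulum stress and chaperone list had a positive log2 fold change against control, with a median of 1.11. DNAJB9, a co-chaperone of the unfolded protein response, had the smallest p of that list, at 2.67 ± 0.42 (6.35-fold, adjusted p = 0.458). Of 25 cytokines and inflammatory mediators, 22 had a positive fold change, with a median of 0.98. Contractile genes pointed the other way, with 27 of 29 negative and a median of −0.78.

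Adjusted over the list alone, 20 of the 25 endoplasmic reticulum genes rose (camera adjusted p = 1.3e-32; adjusted p = 0.106 with an estimated correlation). The list's median was 1.63, 0.87 and 1.04 on slides 1, 2 and 3. Adjusted over the list alone, 10 of the cytokines rose, and the list passed camera with the preset and with an estimated correlation (adjusted p = 4.7e-17 and 0.0188; 0.161 estimated with the slide as a block). Its median was 1.31, 0.85 and 0.83 on the 3 slides. Genes of the amino acid response and serine-glycine synthesis had a median of 0.53, with 30 of 37 positive (camera adjusted p = 4.9e-12; adjusted p = 0.293 with an estimated correlation). Antioxidant genes (0.31) and cholesterol synthesis genes (0.26) lay higher by camera at adjusted p = 0.0061 and 0.0069, and at adjusted p = 0.736 and 0.935 with an estimated correlation. The cholesterol median turned to −0.10 without control replicate 2.

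The matrix groups lay lower with cyclosporine. Of 45 non-collagen matrix genes 40 were negative, with a median of −0.61 (camera adjusted p = 1.1e-10; adjusted p = 0.207 with an estimated correlation). The contractile list passed camera at adjusted p = 5.7e-12 (adjusted p = 0.207 with an estimated correlation). Collagen chains had a median of −0.34, Wnt genes −0.28 and the BMP pathway −0.33, with camera adjusted p = 0.0085, 0.0085 and 0.0366, and adjusted p = 0.736, 0.106 and 0.2 with an estimated correlation. Without the array that stands apart, the BMP list gave adjusted p = 0.0545. Adjusted over the list alone, 1 Wnt gene fell and 1 antioxidant gene rose, and no member of the matrix, collagen, BMP, contractile, amino acid or cholesterol lists passed.

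Neither the genes of the drug's direct targets, calcineurin and cyclophilins, with a median of −0.03 (camera adjusted p = 0.73), nor the NFAT factors and calcineurin-dependent genes downstream of them, at −0.17 (camera adjusted p = 0.963), passed. RCAN1, a textbook calcineurin reporter, gave 0.07 ± 0.22. The remaining 14 lists did not pass either (adjusted p = 0.276 to 0.963). Their medians were −0.32 for TGF-β feedback, −0.09 for collagen processing, 0.19 for metalloproteinases, 0.15 for protease inhibitors, −0.24 for the cell cycle, 0.08 for interferon response and 0.13 for glycolysis. They were −0.07 for p53 targets, 0.33 for lipofibroblast genes, 0.08 for glycosaminoglycan synthesis, −0.07 for integrins, and −0.20, −0.10 and 0.00 for epithelial, endothelial and leukocyte markers.

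The 5 genes with the smallest p were DNAJB9, the cadherin CDH15 (2.77 ± 0.47), the acetyl-CoA transporter SLC33A1 (1.52 ± 0.24), the stress sensor kinase ERN1 (1.47 ± 0.25) and the RNA editing enzyme ADARB1 (−1.43 ± 0.24), all at adjusted p = 0.458. Among the fixed genes, MMP1, interstitial collagenase, gave 3.18 ± 1.52, ACTA2 −1.49 ± 0.96, CCN2 −1.32 ± 0.34, COL1A1 −1.03 ± 0.42, TIMP1 0.37 ± 0.41 and FN1 0.07 ± 0.27. RCAN1 turned to −0.02 without control replicate 1, and FN1 to −0.09 without cyclosporine replicate 1.

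limma called 0 genes, with 1002 at an unadjusted p under 0.05, or 5.28%. That is near the share of 0.05 that no change would give, but this fit has no slide term. The share was 9.90% with the slide block and 8.79% without the array that stands apart. With both changes it was 21.6%, and leaving out that array was chosen after seeing the data. The 0 calls therefore do not show that no gene changed. Array weights and the slide block each called 1 gene, which under the block was CDH15 (adjusted p = 0.0035). With the block and without the array that stands apart, a setting chosen after seeing the data, 77 genes passed, 63 upward and 14 downward. They included DNAJB9 (adjusted p = 0.0191) and, named after their values were seen, the neutrophil chemokines CXCL8 (5.39, adjusted p = 0.0313), CXCL2 (4.97, 0.0191), CXCL1 (3.66, 0.0278) and CXCL6 (2.34, 0.0278), and the chaperones PDIA4 (1.25, 0.0278) and DNAJC3 (1.44, 0.0463).

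**Figure D3:**
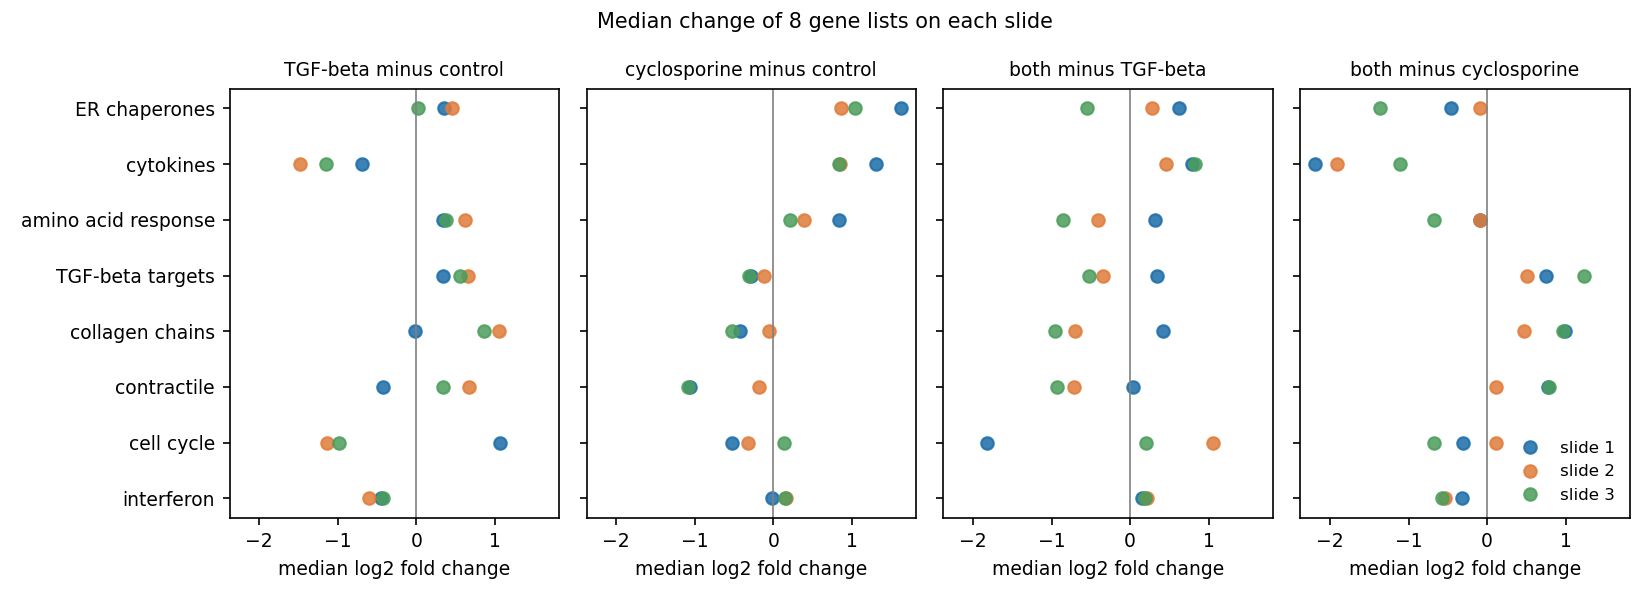
Median log2 fold change of 8 gene lists on slides 1, 2 and 3 (coloured points) in 4 comparisons. The endoplasmic reticulum list lies at 1.63, 0.87 and 1.04 for cyclosporine minus control, and at 0.62, 0.27 and −0.54 for both agents minus TGF-β1.

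The combined treatment changed 356 genes against control, 163 upward and 193 downward. All had 1 sign on the 3 slides, which the choice of called genes largely set. PRG4, again below background on every control array, rose at least 131-fold (mean −7.71 to 1.17), COMP rose by 6.58 ± 0.96 (95.6-fold, adjusted p = 0.0117; 7.59 without the array that stands apart), and SYTL5 by 6.25 ± 0.65. The largest falls included SLC7A14 (−5.85 ± 0.68; −6.47 without that array), CEMIP (−5.55 ± 0.78), FGL2 (−5.06 ± 0.61) and ADAMTS9, a matrix-cleaving protease well above background on 1 of 3 combined arrays (−4.45 ± 0.72). SPP1 rose at least 32.1-fold (−7.11 to −0.85), SLCO2A1 at least 53.9-fold (−6.11 to −0.10), TYRP1 at least 23.1-fold (−7.50 to −1.33, adjusted p = 4.1e-05) and PI16 at least 22.5-fold (−6.81 to −1.37). These bounds, and that of PRG4, include the array that stands apart. Probes dim on the other arrays had a median signal of 378 there, against 5.20 to 6.78 on the others. The bounds were not recomputed without it, so they are not safe minima. Their excess over the bounds with TGF-β1 alone does not show that cyclosporine added to the rise. The matrix protein SVEP1 fell by 4.10 ± 0.45, PDGFD by 3.92 ± 0.84 (by 4.92 without that array) and the lipid phosphatase PLPP3 by 3.80 ± 0.55.

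Of the 32 TGF-β feedback genes, 9 rose and none fell (15 and 2 adjusted over the list alone), with NOX4 at 4.39 ± 0.67, BHLHE40 at 3.15 ± 0.51 and SPHK1 at 3.07 ± 0.56 (camera adjusted p = 8.8e-05; adjusted p = 0.318 with an estimated correlation). Of the 25 endoplasmic reticulum genes 24 were positive, with a median of 0.44, and 3 rose adjusted over the list alone (camera adjusted p = 1.6e-04; adjusted p = 0.774 with an estimated correlation). On slides 1 and 2 that median was 1.08 and 0.77, and on slide 3, which holds the array that stands apart, −0.50. Antioxidant genes had a median of −0.66, with the secreted dismutase SOD3 falling by 2.33 ± 0.50, and 2 fell adjusted over the list alone (camera adjusted p = 8.3e-04; adjusted p = 0.774 with an estimated correlation; adjusted p = 0.0845 without the array that stands apart). Interferon genes had a median of −0.37, with IFIT1 falling by 3.33 ± 0.64 and no other call over the list alone (camera adjusted p = 0.0179; adjusted p = 0.318 with an estimated correlation).

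The other 22 lists did not pass camera (adjusted p = 0.0623 to 1.0). Among collagen chains (median 0.28), COL10A1 rose by 3.52 ± 0.50 and COL7A1 by 1.74 ± 0.33 while COL6A1 fell by 1.35 ± 0.24. Among matrix genes (−0.22), fibulin-1, FBLN1, fell by 2.51 ± 0.34, FBN2 by 2.72 ± 0.43 and NID2 by 2.61 ± 0.43. Other called members were EGR2 (4.21 ± 0.79), FZD8 (4.44 ± 0.59), XYLT1 (3.36 ± 0.33), TNFAIP6 (3.33 ± 0.35), CDH2 (3.04 ± 0.37), P4HA3 (1.27 ± 0.26), SERPINE2 (1.59 ± 0.26) and TIMP1 (2.00 ± 0.41), which rose. The mitotic kinase AURKA (−2.65 ± 0.57), the sterol enzyme LSS (−1.36 ± 0.29), ADM (−3.01 ± 0.58), STC2 (−1.65 ± 0.28) and the transcription factors CEBPD (−2.26 ± 0.43) and ATOH8 (−1.68 ± 0.32) fell. RCAN1 gave −0.78 ± 0.22 and FN1 0.53 ± 0.27. ACTA2 gave 0.30 ± 0.96 (−0.18 without control replicate 1), COL1A1 0.29 ± 0.42, MMP1 1.55 ± 1.52 (2.76 without the array that stands apart) and CCN2 −0.22 ± 0.34 (0.13 after quantile normalization).

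With the slide block 1215 genes passed, which included all 356. Without the array that stands apart 355 passed, of which 220 were among the 356. CSF1R, TEK, ADM, AURKA, LSS, SOD3, CEBPD and P4HA3 were among those lost, and they passed when that array was left out with the slide block, which called 2684 genes. The count was 37, 31 and 167 without control replicates 1, 2 and 3, and 70 and 216 without combined replicates 1 and 2. Quantile normalization moved the median of all genes to −0.18, and split its 238 genes into 136 upward and 102 downward.

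Adding cyclosporine to TGF-β1 left no gene past the threshold against TGF-β1 alone, and the cytokine list stood highest among the groups. Of its 25 genes 24 were positive, with a median of 0.73 (camera adjusted p = 7.5e-08; adjusted p = 0.176 with an estimated correlation). Contractile genes lay lower, with 26 of 29 negative and a median of −0.57 (camera adjusted p = 3.0e-07; adjusted p = 0.549 with an estimated correlation), though not on slide 1: their median was 0.03, −0.72 and −0.93 on slides 1, 2 and 3. The gene with the largest value among the 5 smallest p was HKDC1, a hexokinase family member, at 3.05 ± 0.63 (2.31 without the array that stands apart), with ZG16B at 1.39 ± 0.28, the hexokinase HK3 at 1.57 ± 0.37, the autophagy gene ATG14 at 1.57 ± 0.38 and the sodium-calcium exchanger SLC8A1 at −0.90 ± 0.22, all at adjusted p = 0.896.

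Collagen processing genes had a median of −0.32 with 25 of 26 negative, the amino acid response −0.31 with 36 of 37 negative, and calcineurin and cyclophilins −0.24 with 17 of 17 negative. Their camera adjusted p was 3.3e-04, 1.5e-04 and 0.0056, and adjusted p = 0.525, 0.761 and 0.629 with an estimated correlation. The amino acid median was 0.32, −0.41 and −0.86 on slides 1, 2 and 3, with 32 of 37 genes positive on slide 1. Non-collagen matrix genes (−0.30; 0.20, −0.38 and −0.77 on the 3 slides) and glycolysis genes (−0.26) lay lower at camera adjusted p = 0.0077 and 0.0011, and both at adjusted p = 0.761 with an estimated correlation. Without the array that stands apart, collagen processing, amino acid, calcineurin and glycolysis lists no longer passed (adjusted p = 0.127, 0.528, 0.548 and 0.548), nor did the matrix list (0.117; 0.0069 with the slide block). The metalloproteinase list then passed instead, with a median of 0.50 (adjusted p = 9.9e-04; adjusted p = 0.301 with an estimated correlation). Quantile normalization moved the median of all genes to −0.13 and turned the camera direction of the collagen processing, matrix and amino acid lists upward, none of them called.

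The endoplasmic reticulum list had a median of 0.18 (camera adjusted p = 0.141), with 0.62, 0.27 and −0.54 on slides 1, 2 and 3. With the slide block and without the array that stands apart, its median was 0.59, with 24 of 25 positive and 9 rising adjusted over the list alone (camera adjusted p = 7.2e-13; adjusted p = 0.48 with an estimated correlation). The other 18 lists did not pass in the fit of all 12 arrays (adjusted p = 0.0506 to 0.859), and no member of any list passed adjusted over the list alone. TGF-β feedback genes had a median of −0.01 and collagen chains −0.28. Cell cycle genes had medians of −1.82, 1.05 and 0.20 on slides 1, 2 and 3.

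The fixed genes gave ACTA2 −0.83 ± 0.96, FN1 −0.45 ± 0.27, MMP1 1.12 ± 1.52 (2.33 without the array that stands apart) and TIMP1 0.04 ± 0.41. CCN2, COL1A1 and RCAN1 gave −0.30 ± 0.34, −0.24 ± 0.42 and −0.20 ± 0.22, and CCN2 and COL1A1 turned to 0.01 and 0.06 after quantile normalization. limma called 0 genes, with 469 at an unadjusted p under 0.05, or 2.47%. That is below the share of 0.05 that no change would give, so the 0 calls do not show that no gene changed. Array weights, the slide block, and the block without the array that stands apart also called 0. Without TGF-β1 replicate 1 the count was 6.

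With cyclosporine present, TGF-β1 changed 156 genes, 120 upward and 36 downward. All had 1 sign on the 3 slides, which the choice of called genes largely set. PRG4 rose at least 137-fold (mean −7.90 with cyclosporine alone, 1.17 with both agents), COMP by 6.84 ± 0.96 (115-fold, adjusted p = 0.0113; 7.85 without the array that stands apart) and SYTL5, well above background on 1 of 3 cyclosporine arrays, by 6.55 ± 0.65. SLCO2A1 rose at least 52.9-fold (−6.74 to −0.10) and TYRP1 at least 24.3-fold (−7.22 to −1.33, adjusted p = 6.5e-05), and SYT12, a synaptotagmin, rose by 6.10 ± 0.85. The bounds of PRG4, SLCO2A1 and TYRP1 again include the array that stands apart and are not safe minima. The largest falls were SLC7A14 (−5.16 ± 0.68; −5.78 without that array), the chemokine CXCL1 (−4.24 ± 0.80), FGL2 (−3.37 ± 0.61) and HGF, the hepatocyte growth factor (−3.14 ± 0.26, adjusted p = 0.0021). COL4A6 fell by 2.93 ± 0.53, SVEP1 by 2.93 ± 0.45, LY6K by 2.92 ± 0.46 and the mitochondrial dismutase SOD2 by 2.77 ± 0.36.

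Of the 32 TGF-β feedback genes, 6 rose and none fell, and 16 rose adjusted over the list alone. NOX4 rose by 5.33 ± 0.67, the endothelin gene EDN1 by 3.26 ± 0.61, the receptor-degrading PMEPA1 by 2.28 ± 0.44 and LTBP2 by 2.05 ± 0.28 (list median 0.75, camera adjusted p = 1.4e-09; adjusted p = 0.0598 with an estimated correlation). Of 25 cytokines, 4 fell and 1 rose (13 and 1 adjusted over the list alone), with a median of −1.70 (camera adjusted p = 3.9e-09; adjusted p = 0.0654 with an estimated correlation). The NF-κB inhibitors NFKBIA and TNFAIP3 fell by 1.95 ± 0.38 and 1.68 ± 0.31 while TNFAIP6 rose by 2.65 ± 0.35. Antioxidant genes had a median of −0.78, with SOD2 called and 4 falling adjusted over the list alone (camera adjusted p = 1.4e-09; adjusted p = 0.241 with an estimated correlation).

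Of the 45 matrix genes 5 rose and 1 fell (15 and 5 adjusted over the list alone), among them BGN, biglycan, by 1.81 ± 0.30 and the microfibril gene MFAP2 by 2.00 ± 0.26. Collagen chains had a median of 1.19, with COL10A1 rising by 3.60 ± 0.50 (7 rose and 3 fell adjusted over the list alone). Both lists gave camera adjusted p = 4.5e-04, and adjusted p = 0.392 with an estimated correlation. Contractile genes had a median of 0.51, with CDH2 rising by 2.51 ± 0.37, and integrins 0.36, with ITGA7 rising by 2.32 ± 0.44 (camera adjusted p = 1.5e-05 and 0.0382; both adjusted p = 0.392 with an estimated correlation; integrins 0.0893 with the slide block). All 25 endoplasmic reticulum genes were negative, with a median of −0.63, and −1.37 on slide 3 against −0.46 and −0.09 on slides 1 and 2 (camera adjusted p = 7.9e-07; adjusted p = 0.392 with an estimated correlation). Interferon genes had a median of −0.38 (camera adjusted p = 4.5e-04; adjusted p = 0.0654 with an estimated correlation). The amino acid (−0.29), cholesterol (−0.33), p53 (−0.24) and leukocyte marker (1.08) lists passed camera at adjusted p = 0.0025, 0.0389, 0.0228 and 0.0354, and not with an estimated correlation (0.613, 0.686, 0.435 and 0.392). Without the array that stands apart, the adjusted p of these 4 was 0.67, 0.3, 0.561 and 0.212. Under quantile normalization, which moved the median of all genes to −0.17, the camera direction of the amino acid list turned upward.

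The other 13 lists did not pass (adjusted p = 0.0985 to 0.835), with EGR2 (4.48 ± 0.79), XYLT1 (3.18 ± 0.33) and SERPINE2 (1.33 ± 0.26) called. TIMP1 gave 1.63 ± 0.41 (adjusted p = 0.134; 0.0384 with the slide block), ACTA2 1.79 ± 0.96, COL1A1 1.31 ± 0.42, CCN2 1.11 ± 0.34, FN1 0.47 ± 0.27, RCAN1 −0.85 ± 0.22 and MMP1 −1.63 ± 1.52 (−0.42 without the array that stands apart). With the slide block 444 genes passed, which included all 156; without the array that stands apart 107 passed, of which 80 were among the 156, and with both changes 679. Among those lost without the array were CXCL1, NFKBIA, TNFAIP3, EDN1, BGN, EGR2, COL4A6, SVEP1, LY6K and FGL2, which passed with both changes. The count was 46, 62 and 46 without cyclosporine replicates 1, 2 and 3, and 49 and 77 without combined replicates 1 and 2.

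The interaction asks whether cyclosporine acted differently with and without TGF-β1. No gene passed, but 6 lists differed by camera, led by the endoplasmic reticulum genes: all 25 had a negative interaction, with a median of −0.91 (adjusted p = 6.4e-18; adjusted p = 0.53 with an estimated correlation). Their interaction median was −0.90, −0.52 and −1.43 on slides 1, 2 and 3, and −0.56 with the block and without the array that stands apart. All 37 amino acid response genes were negative, with a median of −0.72 (adjusted p = 6.4e-18; adjusted p = 0.53 with an estimated correlation). Glycolysis genes had a median of −0.43, calcineurin and cyclophilins −0.22, cytokines −0.62 and non-collagen matrix genes 0.33, with camera adjusted p = 0.0024, 0.0117, 0.0117 and 0.0117, and adjusted p = 0.827, 0.785, 0.66 and 0.827 with an estimated correlation. The matrix and cytokine values lay mainly on slide 1, with matrix medians of 1.03, −0.18 and 0.09 and cytokine medians of −1.15, −0.30 and −0.08 on slides 1, 2 and 3. Without TGF-β1 replicate 1 the matrix, cytokine and glycolysis lists gave adjusted p = 0.614, 0.19 and 0.0811. Without the array that stands apart, the glycolysis and calcineurin lists gave adjusted p = 0.293 and 0.365. The antioxidant list (−0.30) did not pass in the fit without a block (adjusted p = 0.0545) and passed with the slide block (0.0238). The other 19 lists did not pass (adjusted p = 0.0926 to 0.985).

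The smallest p values belonged to TSPAN9 (1.46 ± 0.30), ADARB1 (1.71 ± 0.35), ERN1 (−1.58 ± 0.35; 0.12 with the mean of its probes), KIAA1755 (1.96 ± 0.45) and the adrenergic receptor ADRA1B (2.32 ± 0.60), all at adjusted p = 0.996. The fixed genes gave CCN2 1.03 ± 0.48, COL1A1 0.79 ± 0.59, ACTA2 0.65 ± 1.35, RCAN1 −0.28 ± 0.32, FN1 −0.52 ± 0.39 and MMP1 −2.06 ± 2.15 (−0.85 without the array that stands apart), and TIMP1 −0.33 ± 0.58 (0.02 after quantile normalization). limma called 0 genes, with 332 at an unadjusted p under 0.05, or 1.75%. That is below the share of 0.05 that no change would give, so the 0 calls do not show that no interaction exists. Array weights and the block with or without that array also called 0. Quantile normalization moved the median interaction of all genes to −0.15. In simulated data a 2-fold interaction was recovered in 3.83% of genes, a 4-fold interaction in 42.2% and an 8-fold interaction in 68.7%. Those simulated data held no slide effect and no array that stands apart, so recovery in the real data may differ. With the slide block and without the array that stands apart, which also called 0 genes, the recovery was 33.8%, 86.8% and 95.3%.

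The response to TGF-β1 was then set against itself with and without cyclosporine, in 2 comparisons that share no array. Of the 298 genes called without cyclosporine and the 156 called with it, 89 rose and 22 fell in both. None moved in opposite directions. Independent lists of these sizes would share 0.998 and 0.265. Both lists rest on the same variance per gene, which favours the same genes, so that baseline is too low. Across the 298 genes, which are not independent replicates, the fold changes correlated at 0.959 with a slope of 0.802. Those that rose had a median of 2.41 without and 2.19 with cyclosporine, and those that fell −2.19 and −1.30; as the genes were chosen on the first of each pair, its values are biased outward. Across the 156 genes chosen with cyclosporine the correlation was 0.947 and the slope 1.05. Over all genes it was 0.551, with 0.732 without the array that stands apart, 0.398 and 0.401 without combined replicates 1 and 2, and 0.349 without the filter on dim probes. The response to cyclosporine correlated at 0.167 with and without TGF-β1 over all genes, at 0.419 without the array that stands apart and at 0.0167 without combined replicate 1.

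**Figure D4:**
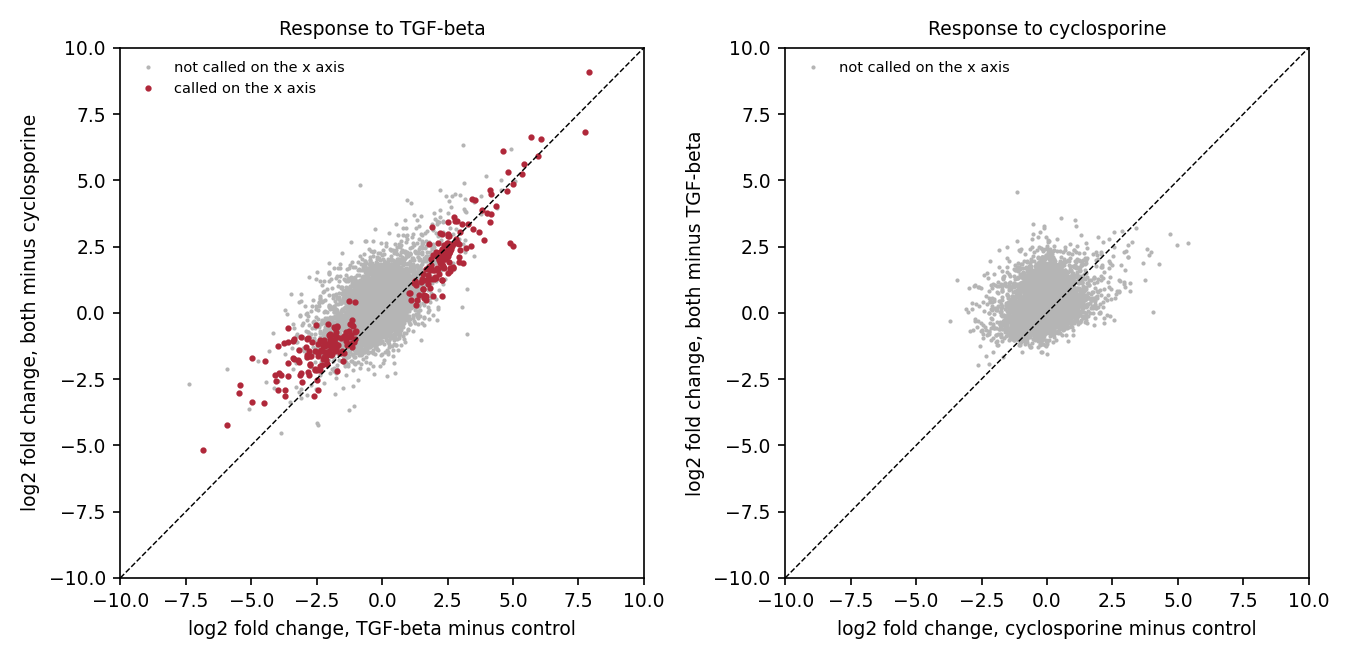
Log2 fold change of each tested gene with the other agent present (y axis) against that without it (x axis), for TGF-β1 (left) and cyclosporine (right); red points passed the threshold on the x axis and the dashed line is equality. The 298 red genes correlate at 0.959 on the left, and all genes on the right at 0.167.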

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

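The count of genes under other splits of the samples and the G+C test were set out in advance; the other tests in this part were chosen only after the result was seen. For each comparison of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. As many genes as in the real split came in 1 of 10 splits for TGF-β1 against control (298, highest other 0), both agents against control (356, highest other 0) and both against cyclosporine (156, highest other 0). The number was 10 of 10 for cyclosporine against control (0, highest other 0) and for both agents against TGF-β1 (0, highest other 60). The split with 60 genes points to a structure of the samples: it puts both arrays of slide 1 on 1 side and both of slide 3 on the other, so it parts only slide 2. The other split with that layout gave 0, so the slides alone do not account for the 60. The 3 other splits that part all 3 slides, as the real one does, gave 0 in every comparison. For the interaction, 100 of 100 splits drawn gave as many genes as the real 0, with a highest other of 13; where the real count is 0 every split reaches it, so these counts decide nothing about chance.

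Control probes that lie near background on the other 11 arrays stood far above it on the array of TGF-β1 plus cyclosporine replicate 3, a signal in data outside the comparisons: their median was 401, against 4.99 to 6.52 elsewhere. Light added over the whole array is argued against as the whole cause by the negative control spots: their median there, 25.6, was above the 4.84 to 6.47 elsewhere, so a small added light stays open, but lay far below 401. RNA of another human cell type is argued against by the same control probes, at 61.6 times their highest median on the other arrays, since such RNA would raise probes for human genes and leave these controls near background. Hybridisation that depends on base composition more than on sequence stays open as a candidate explanation: among 8386 probes dim on the other arrays, signal on this array correlated with G+C percent at 0.544, against 0.0407 to 0.311 elsewhere. These probes were picked for lying near background on the other arrays, which holds the correlations there down. The contrast between arrays therefore cannot decide for or against this explanation. The design gives no biological explanation for a single array, and none was tested.

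The effect of cyclosporine differed with and without TGF-β1, by the interaction test with camera's preset correlation, in 6 gene lists: endoplasmic reticulum stress (adjusted p = 6.35e-18), the amino acid response (6.35e-18), glycolysis (0.0024), non-collagen matrix (0.0117), calcineurin and cyclophilins (0.0117) and cytokines (0.0117). None of the 6 passed with an estimated correlation (adjusted p = 0.53, 0.53, 0.827, 0.827, 0.785 and 0.66 in that order), and without the array that stands apart glycolysis (0.293) and calcineurin (0.365) did not pass either. The matrix and cytokine interactions lay mainly on slide 1, whose TGF-β1 array is apart from replicates 2 and 3: the medians on slides 1, 2 and 3 were 1.03, −0.18 and 0.09 for matrix and −1.15, −0.30 and −0.08 for cytokines. For the endoplasmic reticulum list, all 25 genes had a negative interaction. The array that stands apart is argued against as the whole cause, since the median interaction without it and with the slide block was −0.56, against −0.91 with it. Genes of the list moving together from array to array stay open, as the adjusted p was 0.53 with an estimated correlation. A weaker effect of cyclosporine on these chaperones in cells given TGF-β1 is the biological explanation that the design names, and it may hold beside that one.

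TGF-β1 replicate 1 lay apart from replicates 2 and 3 in the response to TGF-β1. A swap with the array of both agents on the same slide is argued against by the endoplasmic reticulum list, whose median for both agents minus TGF-β1 on slide 1 was 0.62, the direction of cyclosporine. The scanner or software of slide 1 is argued against by cyclosporine's fold changes, which correlated between slide 1 and the others at 0.637 or more. The cell cycle state of that culture stays open and could account for part of it: the cell cycle list had a median of 1.07 on slide 1, against −1.14 and −0.99 on slides 2 and 3.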

How the results depend on the processing

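The settings that leave out TGF-β1 plus cyclosporine replicate 3 where it is in neither group, or join that to the slide block, were chosen only after the data were seen, and the others were planned. For TGF-β1 against control, both agents against control and both against cyclosporine, 43, 44 and 30 called genes under the naming rule were examined here. They kept their direction in all of their 602, 572 and 390 values, of which 177, 185 and 102 no longer passed. As they were chosen for being called, many without overlap between groups, their direction was largely set by that choice. The value table also holds the same data as the scanner files. Values of called lists are given next for TGF-β1, cyclosporine and both against control, both against TGF-β1, both against cyclosporine, and the interaction. Failing with direction kept were 23 of 165, 28 of 150, 10 of 56, 32 of 98, 48 of 182 and 32 of 120. A further 0, 1, 0, 5, 2 and 0 reversed, and none of those passed. The uncalled genes examined are given in the same order. They passed in 7 of 84, 13 of 308, 2 of 78, 0 of 156, 5 of 91 and 0 of 228 values. The interaction had 0 genes in all 26 alternatives. The slide block changed no call of a named gene or list beyond those in the report. Where no reason is given below, the cause was not tested.

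At an adjusted p under 0.01, TGF-β1 against control had 49 genes, both against control 51 and both against cyclosporine 37, since the threshold is stricter. With only the compared groups in the fit, which leaves fewer arrays, TGF-β1 against control had 216 genes (67 upward and 149 downward), both against control had 101 and both against cyclosporine 32. Across called genes only, the TGF-β1 responses correlated at 0.959 and 0.947, as genes with large changes were chosen. With camera's correlation estimated, the numbers of lists called were 0 for TGF-β1 against control, 1 for cyclosporine against control, 0 for both against control, 0 for both against TGF-β1, 0 for both against cyclosporine and 0 for the interaction; with fry they were 2, 2, 2, 0, 4 and 0.

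Quantile normalization gave 187 genes for TGF-β1 against control, and 10 lists for both against control and 3 for both against TGF-β1. It turned CCN2 to 0.13 in both against control and 0.012 in both against TGF-β1, COL1A1 to 0.064 in both against TGF-β1 and the interaction of TIMP1 to 0.023. In both against TGF-β1 it turned the camera direction of collagen processing (median −0.10), non-collagen matrix (−0.091) and the amino acid response (−0.086), and in both against cyclosporine that of the amino acid response (−0.066).

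Normexp with the 75th percentile gave 107, 73 and 54 genes for TGF-β1 against control, both against control and both against cyclosporine, and moved the median of all genes to −0.10 in cyclosporine against control; CCN2 in TGF-β1 against control was −0.019. Normexp with quantile normalization gave 10 lists for both against control and 4 for both against TGF-β1. CCN2 was then 0.14 in both against control and 0.071 in both against TGF-β1, and COL1A1 0.058 in the latter. The camera direction turned for non-collagen matrix (−0.093) and the amino acid response (−0.068) in both against TGF-β1, and for the amino acid response (−0.077) in both against cyclosporine. That scaling moved the median of all genes to −0.13 in both against control, −0.10 in both against TGF-β1, −0.13 in both against cyclosporine and −0.11 in the interaction.

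Without the filter on dim probes the counts were 59, 67 and 44, with 8 lists for both against control and 12 for both against TGF-β1, and the cyclosporine responses correlated at 0.0108. The mean of a gene's probes turned the interaction of ERN1 to 0.12. Trended and robust variances gave 603 genes for both against control and 237 for both against cyclosporine. Array weights gave 1423, 1496 and 357 genes, and 1 for cyclosporine against control. The replicate block gave 648, 1215 and 444, and 1 for cyclosporine against control, and the slide block, being the same factor, the same 648, 1, 1215 and 444. With the block and without the array that stands apart the counts were 2787, 77, 2684 and 679; RCAN1 in both against TGF-β1 was 0.015, the interaction of TIMP1 0.11, and the cyclosporine responses correlated at 0.439.

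Leaving out 1 array at a time, TGF-β1 against control had 48 to 580 genes, both against control 31 to 355, both against cyclosporine 46 to 107 and both against TGF-β1 0 to 6. The numbers of lists ran from 10 to 17 for TGF-β1 against control, 3 to 8 for both against control and 4 to 10 for the interaction, and the cyclosporine responses correlated at 0.0167 to 0.419. The low and high arrays left out are named next. In TGF-β1 against control CCN2 ran from −0.050 (TGF-β1 replicate 3) to 0.28 (TGF-β1 replicate 1), and MMP1 from −1.42 (TGF-β1 replicate 1) to 1.44 (TGF-β1 replicate 3). In cyclosporine against control FN1 ran from −0.086 (cyclosporine replicate 1) to 0.23 (cyclosporine replicate 3), RCAN1 from −0.015 (control replicate 1) to 0.18 (control replicate 3) and the cholesterol list from −0.10 (control replicate 2) to 0.53 (cyclosporine replicate 2). ACTA2 in both against control ran from −0.18 (control replicate 1) to 0.93 (control replicate 3). Interactions ran from −0.54 (TGF-β1 replicate 1) to 1.30 (TGF-β1 replicate 3) for ACTA2 and −0.70 (combined replicate 1) to 0.22 (combined replicate 3) for TIMP1. In both against TGF-β1, COL1A1 ran from −0.74 (TGF-β1 replicate 1) to 0.062 (TGF-β1 replicate 3) and TIMP1 from −0.33 (combined replicate 1) to 0.59 (combined replicate 3).

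Signal over background limits the dim genes: the filter set aside probes not well above background in any whole group. A fold against a group below background is a lower bound with regard to that background only.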

Other observations

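The haemoglobin genes below were chosen only after their values were seen, and no explanation for them was tested. In cyclosporine against control, all 7 measured had a negative fold change. The fit called 0 of them, and 0 with the slide block and without the array that stands apart. In both agents against control 5 were negative and 0 were called, against 4 called in that other setting. In TGF-β1 against control, all 7 had a negative fold change as well and 0 were called with limma. HBG1 was below background on every TGF-β1 array (mean −1.13 in control, −7.06 with TGF-β1). Against that background its mean lay at least 24.5-fold lower, without regard to the spread between arrays. Its fold change was −5.94 ± 1.62 (adjusted p = 0.127), with −3.43, −7.71 and −6.68 on slides 1, 2 and 3. HBD gave −5.08 ± 1.77 and HBE1 −2.71 ± 0.95 (both adjusted p = 0.267), HBB −2.44 ± 1.58 (0.719), HBA2 −0.93 ± 0.81 (0.865), HBZ −0.76 ± 0.90 (0.951) and HBA1 −0.11 ± 0.94 (0.999). With the slide block and without the array that stands apart, 5 of the 7 passed: HBG1, HBD, HBE1, HBB and HBA2 at adjusted p = 0.02, 0.0059, 0.0239, 0.0166 and 0.0362, while HBZ and HBA1 gave 0.195 and 0.731.

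Across the 77 genes that passed for cyclosporine against control in that same setting, chosen after seeing the data, the fold changes with and without TGF-β1 correlated at 0.850, with a slope of 0.378. These genes were picked on the fold change without TGF-β1, which biases it outward, and genes are not independent replicates.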
